A study of Mus musculus with 25 samples.

How the data were processed

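The measurement was 3' end sequencing of polyadenylated RNA from hepatocytes of C57BL/6 mice, in 25 libraries: 5 from mice on normal diet and 20 from mice on a NASH-inducing diet, 4, 3, 4, 3, 3 and 3 of them after 1 to 6 weeks. Per the labels, livers were perfused with collagenase, hepatocytes were pelleted at low speed and then sorted by flow cytometry (the gate is not given in the sources used here), and libraries were made with the QuantSeq 3' FWD kit. The submitters' processing notes name FastQC, cutadapt, STAR 2.7.1a and the mouse build GRCm39. The counting tool and the annotation are not given in the sources used here. The deposited table holds raw counts per gene symbol, 1 column per library, which was checked on the values: whole numbers of at least 0 whose totals differed between libraries.

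Totals were 5.28e+06 to 1.002e+07 counts per library. Of 37085 symbols, 11869 were tested, those kept by the edgeR filter (filterByExpr) by group. Genome positions were not used, since the build of the reference at hand differs from that of the counts. No 2 libraries of the same group were copies of each other: the disagreement of each such pair, as chi-squared over degrees of freedom, was between 5.77 and 35.1. The median gene-wise biological coefficient of variation was 0.179.

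Differences between groups were tested with edgeR 4.0.16 in R 4.3.3, with TMM composition factors and robust quasi-likelihood F-tests. One model of 7 groups held all 25 libraries (18 residual degrees of freedom), and contrasts gave each week against normal diet, week 6 against week 1, the linear slope over the means of weeks 1 to 6, and any difference among those weeks. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Standard errors of log2 fold changes were taken as the size of the change over the square root of its F statistic. Levels are composition-scaled counts per library total (CPM), and log2 levels use a prior count of 2.

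Gene lists were tested as sets with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists within a comparison. Each list with at least 3 tested members entered, which all 43 did. Members were counted as higher or lower after adjustment over all genes and, separately, adjusted over the list alone. The hepatocyte lists were cholesterol synthesis and uptake, fatty acid synthesis, fatty acid oxidation and ketogenesis, lipid droplet and lipid uptake, lipoprotein export, bile acid synthesis and transport, xenobiotic metabolism, oxidative stress response, endoplasmic reticulum stress, integrated stress response, acute phase proteins, chemokines and NF-kB targets, interferon response, complement and coagulation, hepatocyte transcription factors, hepatocyte secreted proteins, pericentral zonation, periportal zonation, urea cycle and amino acid catabolism, methionine, choline and one-carbon metabolism, glucose metabolism, oxidative phosphorylation, mitochondrially encoded transcripts, ribosomal proteins, lysosome and autophagy, cell cycle, p53 targets, hepatocyte injury and YAP targets, cytoskeleton, oncofetal genes, immediate early and heat shock genes, circadian clock, male-biased liver genes and female-biased liver genes. The marker lists were those of Kupffer cells; monocytes, macrophages and dendritic cells; sinusoidal endothelial cells; stellate cells and myofibroblasts; cholangiocytes; lymphocytes; neutrophils; erythroid cells; and sex chromosome genes. Membership overlaps: 10 of the 20 tested periportal genes are in another list, as are 7 of 26 xenobiotic, 5 of 19 pericentral, 5 of 20 male-biased and 5 of 22 transcription factor genes, while the cholesterol, Kupffer, endothelial and stellate lists share 0 members. On normal diet 10 of 15 Kupffer, 13 of 18 endothelial, 9 of 19 monocyte and 3 of 16 stellate markers reached at least 10 CPM.

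The comparisons, lists, most alternatives and the rule for naming genes were set before the data were examined. The rule names, per comparison of 2 groups, the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 CPM and no overlap between the libraries of both groups. Symbols of the form Gm with digits or ending in Rik were passed over. For the trend it names the 6 steepest each way without the overlap condition, for the test among weeks the 6 smallest p-values, from each list up to 4 members with the smallest p, and for the libraries the 10 genes with the largest share of counts. Results of single genes that are withheld are not reported here. Non-overlap counts are given beside the share that chance gives for the group sizes.

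Alternatives changed 1 choice at a time: the median-of-ratios size factors of DESeq2 or library size only in place of TMM, no filter or a stricter one of 5 CPM in 3 libraries, DESeq2 1.42.0 or limma voom in place of edgeR, only both compared groups in the model, weeks as a number for the trend, the replicate numbers as a block, each library left out in turn, a threshold of 0.01 or at least a 2-fold change, and for lists an estimated correlation or the rotation test fry. After the data were seen, 4 more were added: the marker score (mean of the Kupffer, endothelial and stellate lists per library) as a term, normal-diet libraries 1 and 5 left out, mitochondrially encoded genes left out, and each library thinned to the smallest total. The correlation of fold changes between weeks was set beside simulations of unchanged groups that share the same normal-diet libraries, and it and the overlap beside splits of these libraries into 2 and 3.

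The tests were tried on simulated data with known changes among 11869 genes. With 4 against 5 libraries (week 1) edgeR recovered 23.9% of 1.5-fold, 53.7% of 2-fold and 90.9% of 4-fold changes, and 3 of 124 calls were false. With 3 against 5 (week 6) it recovered 20.9%, 64.2% and 81.8%, and 3 of 118 calls were false. DESeq2 made 12 false calls among 142 in the week 1 simulation. A list of 20 genes changed 1.5-fold was called in both (camera adjusted p = 2.1e-24 and 2.1e-18), with 0 of 43 other lists. The genes were simulated independently of each other. The simulation therefore cannot tell how often lists are called falsely where genes correlate.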

Results

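Polyadenylated RNA was measured in hepatocytes sorted from the livers of C57BL/6 mice, by sequencing tags from the 3' ends of transcripts. The series follows mice through up to 6 weeks of a diet that induces non-alcoholic steatohepatitis (NASH), in which fat builds up in the liver and is joined by inflammation and scarring. Its question is how gene expression in hepatocytes differs between mice on a normal diet and mice after each length of time on the NASH diet. The 25 libraries form 7 groups: 5 on normal diet, and 4, 3, 4, 3, 3 and 3 after 1, 2, 3, 4, 5 and 6 weeks. The composition of the diet and the ages of the mice are not given in the sources used here. The labels number the libraries within each group without saying that each is a separate mouse, so p-values measure the spread between these libraries.

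Each library held between 5.28e+06 and 1.002e+07 counts. Of 37085 gene symbols in the table, 20520 had at least 1 count and 11869 were tested. The mitochondrial ribosomal RNA mt-Rnr2 took 6.99% of the counts on average and Alb, the gene of serum albumin, 5.50%, followed by mt-Nd2 (4.27%), mt-Nd4 (3.86%), mt-Rnr1 (3.15%), Apoe (2.51%), mt-Cytb (1.95%), mt-Nd1 (1.26%), Serpina3k (1.09%) and Apoa1 (1.06%). Between 21.3% and 23.3% of the counts were mitochondrially encoded in the group means. The first principal component held 44.9% of the variance, with group means of -39.8 ± 24.4 on normal diet, 17.3 ± 21.5 at week 4, 60.8 ± 5.50 at week 5 and 48.6 ± 9.31 at week 6 (SD).

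Composition factors (TMM) rose from a mean of 0.905 ± 0.0323 on normal diet to 1.14 ± 0.0176 at week 5 and 1.12 ± 0.0306 at week 6 (SD). Scaling by library size alone instead moved the median log2 fold change of all tested genes up by 0.12, 0.09, 0.10, 0.16, 0.33 and 0.30 at weeks 1 to 6, by 0.18 for week 6 against week 1 and by 0.05 per week for the trend. Every change given here is therefore relative to the composition-scaled median, and the split of calls into higher and lower is also given for library size alone. A log2 fold change is printed with its standard error, and levels in CPM (counts scaled by library total and composition) with the SD.

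Transcripts that mark other liver cells were present in these sorted hepatocyte libraries, and their levels were higher in the later weeks. The sinusoidal endothelial list averaged 4.01 ± 0.89 log2 CPM on normal diet (SD, n = 5), 5.42 ± 0.65 at week 4, 6.46 ± 0.09 at week 5 and 6.13 ± 0.21 at week 6 (SD, n = 3 each). For Kupffer cells, the resident macrophages of the liver, the means were 3.99 ± 1.04, 5.46 ± 0.55, 6.43 ± 0.07 and 6.24 ± 0.05 in the same groups. Stellate cells and myofibroblasts, the collagen-producing cells, gave 1.61 ± 0.36, 3.18 ± 0.54, 4.25 ± 0.66 and 4.01 ± 0.33, and monocytes, macrophages and dendritic cells 2.04 ± 0.83, 3.28 ± 0.57, 4.55 ± 0.32 and 4.66 ± 0.18. Among the most abundant members, Cd5l of the Kupffer list stood at 93.2 ± 58.5 CPM on normal diet and 469 ± 97.7 at week 6, and Aqp1 of the endothelial list at 86.9 ± 58.1 and 363 ± 109. Ecm1 of the stellate list stood at 25.7 ± 6.93 and 105 ± 15.2, and Lyz2 of the monocyte list at 40.4 ± 20.9 and 211 ± 15.2 (SD, n = 5 and 3). Dcn, of the stellate list, averaged 58.6 and 314 CPM in the same groups. These genes were chosen for their abundance after the values were seen. Averaged over the Kupffer, endothelial and stellate lists, a marker score per library was 3.20 ± 0.736 on normal diet, 3.86 ± 0.535, 4.16 ± 0.627, 3.98 ± 0.328, 4.69 ± 0.522, 5.71 ± 0.169 and 5.46 ± 0.166 at weeks 1 to 6 (log2 CPM, SD). Models with this score as a term are given beside the results below.

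Against normal diet, members of these lists passed the test from week 4 on (edgeR, Benjamini-Hochberg). At week 4, 3 of 15 Kupffer, 3 of 19 monocyte, 10 of 18 endothelial and 11 of 16 stellate members were higher (13, 6, 18 and 14 adjusted over the list alone). At week 5 it was 15, 17, 18 and 15 of them, and at week 6 14, 18, 18 and 15 (15, 18, 18 and 16 adjusted over the list alone at each). List medians at week 6 were 2.04, 2.25, 1.94 and 2.38 (3.0e-10, 1.0e-11, 1.7e-14 and 1.0e-11 as camera adjusted p, and adjusted p = 0.174, 0.124, 0.124 and 0.124 with an estimated correlation). Examples at week 6 are Clec4f (2.04 ± 0.41), Clec1b (2.51 ± 0.39), Stab2 (2.03 ± 0.30) and Lrat (2.34 ± 0.36). Gpnmb, a lysosomal glycoprotein of macrophages that is also in the lysosome list, went from 0.179 ± 0.275 CPM (6 counts in all) to 16.9 ± 4.16 CPM. Camera also gave these 4 lists a shift at weeks 1 to 3, with medians of 0.70, 0.58, 0.24 and 0.80 at week 1, 0.99, 0.79, 0.44 and 1.41 at week 2 and 0.85, 0.83, 0.45 and 0.92 at week 3. Adjusted over the list alone, 10 stellate members were higher at week 2. Each of those calls was lost with an estimated correlation (adjusted p from 0.230 to 0.726 with an estimated correlation over the 3 weeks). Without normal-diet libraries 1 and 5 the week 1 direction turned for the monocyte (camera adjusted p = 0.925) and endothelial lists (0.263). The marker score as a term turned it for both at week 1, for these and the Kupffer list at week 2 and for the endothelial and stellate lists at week 3. Apart from the monocyte list, these lists make up the score, so their turn does not bear on the shift.

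Other marker lists were not called in any comparison with normal diet. Of 7 tested cholangiocyte markers, 4 of which the injury list also holds, 3 were higher at week 6 (list median 0.80, camera adjusted p = 0.214), among them Bicc1 (2.23 ± 0.45) and Spp1 (1.48 ± 0.35). Lymphocyte markers had 1 of 4 higher, Ptprc (1.94 ± 0.41), the common leukocyte antigen, and 1 lower, Cd4 (-1.42 ± 0.49) (camera adjusted p = 0.702). Of the 3 neutrophil markers 1 was higher, Csf3r (2.83 ± 0.52) (camera adjusted p = 0.0801). The erythroid list had a median of -0.42 over 5 tested members at week 6 (camera adjusted p = 0.815), and the sex chromosome list one of -0.23 over 4 that turned positive with library size only (camera adjusted p = 0.423).

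**Figure D1:**
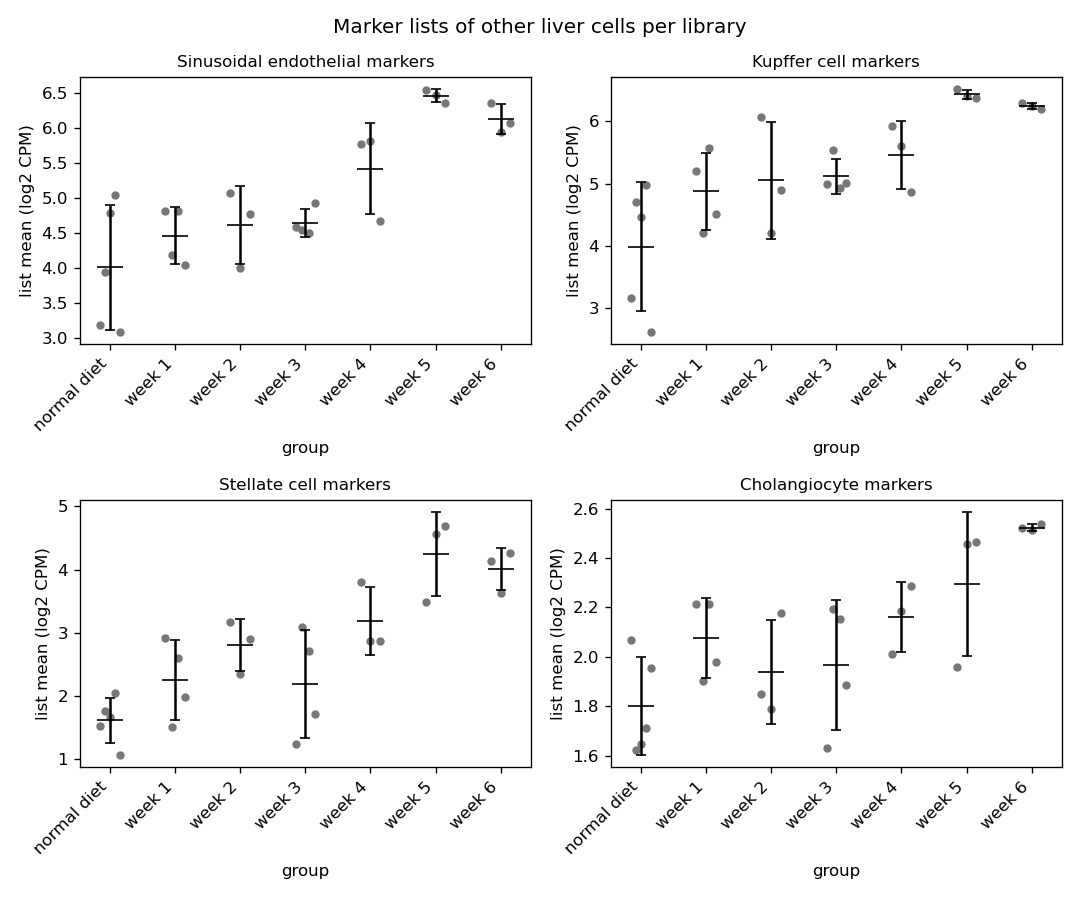
Mean log2 CPM of 4 marker lists (sinusoidal endothelial cells, Kupffer cells, stellate cells and cholangiocytes) in each library, by weeks on the NASH diet, with normal diet at 0. Points are libraries and bars the group mean ± SD; the endothelial mean went from 4.01 ± 0.89 on normal diet to 6.13 ± 0.21 at week 6, and the cholangiocyte mean from 1.80 ± 0.20 to 2.52 ± 0.01.

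The first comparison asks what 1 week of NASH diet did. The genes that make cholesterol were far lower: Sqle, which encodes squalene epoxidase, averaged 63.3 ± 7.01 CPM (SD, n = 5) on normal diet and 3.51 ± 0.928 CPM (SD, n = 4) at week 1. This was a 17.9-fold difference (log2 fold change -4.16 ± 0.23). Fdps (-2.78 ± 0.25), Msmo1 (-2.53 ± 0.28) and Nsdhl (-2.45 ± 0.25), which act before and after squalene in the same pathway, were also lower. Outside this pathway, Cyp17a1, a steroid hydroxylase (-3.58 ± 0.60), and Gsta2, a glutathione transferase (-2.47 ± 0.39), were lower. The genes with the largest rises were Adam11, of the ADAM family (1.97 ± 0.28, from 2.86 ± 1.47 to 11.1 ± 1.29 CPM), and Tsc22d1 (1.61 ± 0.30). Next came Tmem86a (2.82-fold), Lpl, lipoprotein lipase (1.31 ± 0.28), Fabp2, a fatty acid binding protein (1.20 ± 0.18), and Abcg8, part of the transporter that exports cholesterol into bile (1.18 ± 0.25).

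Of 11869 genes tested, 142 differed at week 1 (edgeR, Benjamini-Hochberg adjusted p from 9.5e-12 for Sqle to 0.0177 for Lpl among those named above), 26 higher and 116 lower, and 85 changed at least 2-fold. With library size only the split was 69 higher and 82 lower. In 130 of the 142 genes each library of one group lay above each of the other, as in all genes just named, and of all tested genes 525 did so, where chance gives 1.59% of genes. DESeq2 called 267 genes and the model with the marker score 132, and without normal-diet libraries 1 and 5, which had the lowest marker scores (2.62 and 2.26), 84 were called. Leaving out normal-diet library 5 gave 94 and leaving out week 1 library 2 gave 93.

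By gene list, cholesterol synthesis and uptake fell as a whole: 23 of its 25 tested members were lower (25 adjusted over the list alone), with a median of -1.84 (adjusted p = 1.6e-128, or 7.3e-06 with an estimated correlation). The list averaged 6.04 ± 0.36 log2 CPM on normal diet (SD, n = 5) and 4.27 ± 0.12 at week 1 (SD, n = 4). In fatty acid synthesis 3 of 19 were lower. The list median was -0.69 (adjusted p = 3.3e-09, or 0.298 with an estimated correlation), with 10 adjusted over the list alone. The 3 were Acss2, which makes acetyl-CoA from acetate (-1.90 ± 0.27), Me1, malic enzyme (-1.19 ± 0.27), and Acacb, an acetyl-CoA carboxylase (-1.31 ± 0.32). Fatty acid oxidation and ketogenesis had 1 of 24 higher, also over the list alone, Vnn1 (1.11 ± 0.25), and a median of 0.06 (adjusted p = 0.0154, or 0.439 with an estimated correlation).

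Genes of the periportal zone, the part of the lobule that receives blood first, were lower, and the pericentral list was called higher, a call lost with an estimated correlation. Of 20 periportal members 8 were lower (15 adjusted over the list alone, median -0.61, adjusted p = 1.5e-21, or 0.00180 with an estimated correlation), including Etnppl (-1.32 ± 0.21) and Aldh1b1 (-1.27 ± 0.26). Pericentral zonation had 2 of 19 higher (7 adjusted over the list alone, median 0.87, adjusted p = 2.5e-07, or 0.321 with an estimated correlation): Glul, glutamine synthetase, went from 477 ± 165 to 1049 ± 198 CPM (1.14 ± 0.27), with Lect2 (1.17 ± 0.28). In urea cycle and amino acid catabolism, which shares 7 members with other lists, 6 of 24 were lower (11 adjusted over the list alone, median -0.37, adjusted p = 2.5e-15, or 0.0684 with an estimated correlation), among them Asl and Ass1 of the urea cycle (-0.96 ± 0.17 and -1.19 ± 0.27). Methionine, choline and one-carbon metabolism had 3 of 20 lower: Mat1a (-0.95 ± 0.16), Gnmt (-1.06 ± 0.22) and Cth (-1.18 ± 0.26). Its median stood at -0.36 (adjusted p = 2.8e-10, or 0.0357 with an estimated correlation), and 10 passed adjusted over the list alone. The oxidative stress list had 2 of 22 lower (9 adjusted over the list alone, median -0.27, adjusted p = 1.2e-06, or 0.0346 with an estimated correlation), the glutathione transferases Gsta4 (-1.30 ± 0.21) and Gsta2 (-2.47 ± 0.39).

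Xenobiotic metabolism had 4 of 26 lower at week 1 (6 adjusted over the list alone), with a median of -0.12 that turned to 0.00 with library size only (adjusted p = 0.00716, or 0.400 with an estimated correlation). They were the carboxylesterase Ces2a (-1.01 ± 0.16), the sulfotransferase Sult1a1 (-1.24 ± 0.23), Cyp3a25 (-0.82 ± 0.18) and Cyp3a11, which went from 2344 ± 648 to 666 ± 247 CPM (-1.82 ± 0.39). The Cyp3a genes are close paralogs that may share reads, so their separate values are uncertain. A further 11 lists were shifted by camera although 0 of their 209 members passed in edgeR (27 at an unadjusted p under 0.05, 5 passed in DESeq2 and 0 in voom). They were the 4 marker lists, the chemokine, interferon and injury lists with medians of 0.42, 0.17 and 0.36, and oxidative phosphorylation, mitochondrially encoded transcripts, ribosomal proteins and hepatocyte secreted proteins with -0.17, -0.19, -0.10 and -0.16. Adjusted over the list alone, 1 mitochondrial and 2 secreted protein genes were lower. The ribosomal median turned positive with library size only. Each of these 11 calls was lost with an estimated correlation (adjusted p from 0.206 to 0.664 with an estimated correlation). In all 20 of 43 lists were called, 9 up and 11 down, of which 4 held with an estimated correlation: cholesterol, periportal, one-carbon and oxidative stress.

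After 2 weeks the same sterol genes were lower and a few lipid-handling genes were higher. Sqle (-3.52 ± 0.25), Fdps (-2.55 ± 0.28), Nsdhl (-2.48 ± 0.28) and Msmo1 (-2.46 ± 0.31) were lower, as were Acss2 (-2.24 ± 0.30) and Cyp3a11 (-2.50 ± 0.45). Cfd, the complement factor D also known as adipsin, was higher (4.63 ± 0.83, from 0.743 ± 0.492 CPM on normal diet to 18.7 ± 13.6 at week 2). So were Adam11 (2.05 ± 0.29), Tmem86a (1.80 ± 0.32), the apolipoprotein Apoa4 (2.00 ± 0.41) and both parts of the sterol transporter, Abcg5 (1.55 ± 0.36) and Abcg8 (2.82-fold). In total 105 genes differed (edgeR, Benjamini-Hochberg adjusted p from 1.7e-09 for Sqle to 0.0451 for Abcg5 among those named), 27 higher and 78 lower, and 46 higher and 58 lower with library size only. In 99 of them the groups' libraries did not overlap, as in the genes named, against 818 of all tested genes, where chance gives 3.57%.

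The week 2 count was 198 in DESeq2, 58 with only both compared groups in the model, 59 with the replicate numbers as a block, 49 with the marker score as a term and 51 without normal-diet libraries 1 and 5. It was 44 without week 2 library 1 and 53 without library 2 of that week.

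At week 2, 19 of 25 cholesterol members were lower. As a list it had a median of -1.70 (adjusted p = 1.6e-84, or 1.1e-04 with an estimated correlation), and 25 such members adjusted over the list alone. Lipoprotein export had 3 of 18 higher (4 adjusted over the list alone, median 0.20, adjusted p = 5.2e-04, or 0.397 with an estimated correlation), Apoa4, Abcg5 and Abcg8. Fatty acid synthesis had 2 of 19 lower (4 adjusted over the list alone, median -0.56, adjusted p = 4.8e-04, or 0.612 with an estimated correlation), Acss2 and Acacb (-1.79 ± 0.36). In xenobiotic metabolism 2 of 26 were lower (4 adjusted over the list alone), with a median of -0.21 (adjusted p = 1.6e-04, or 0.230 with an estimated correlation). Oxidative stress had 2 of 22 lower (6 adjusted over the list alone, median -0.32, adjusted p = 8.8e-05, or 0.134 with an estimated correlation). One-carbon metabolism had 1 of 20 lower, Cth (-1.18 ± 0.28), and 4 adjusted over the list alone (median -0.28, adjusted p = 6.8e-08, or 0.134 with an estimated correlation). The glucose list was not called (camera adjusted p = 0.491). The 9 other called lists had 0 of 185 members past the edgeR threshold (58 at an unadjusted p under 0.05, 9 in DESeq2, 0 in voom). These were the 4 marker lists, chemokines (0.70, 2 higher adjusted over the list alone, direction turned with the marker score), periportal zonation (-0.44, 8 lower adjusted over the list alone), the urea list (-0.35), oxidative phosphorylation (-0.19) and ribosomal proteins (-0.13). Of the 15 lists called at week 2, 6 up and 9 down, cholesterol alone held with an estimated correlation, and those 9 had adjusted p from 0.172 to 0.726 with an estimated correlation.

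Week 3 looked much like week 2 in its named genes. Sterol genes stayed lower than on normal diet, with Sqle (-3.52 ± 0.22), Msmo1 (-2.22 ± 0.28), Nsdhl (-2.19 ± 0.25), Fdps (-2.16 ± 0.25) and Hmgcs1 (-2.11 ± 0.31), and Cyp3a11 was lower (-2.39 ± 0.40). Among genes that the rule names, the largest rises were Cfd (5.29 ± 0.79, 29.7 ± 18.9 CPM at week 3), Adam11 (2.37 ± 0.27) and Tmem86a (1.61 ± 0.30). Next came the secreted protein gene Wfdc2 (1.48 ± 0.31), the glutamate transporter gene Slc17a8 (1.35 ± 0.22) and Fabp2 (1.16 ± 0.18). There were 101 genes (edgeR, Benjamini-Hochberg adjusted p from 1.4e-10 for Sqle to 0.0149 for Wfdc2 among those named), 29 higher and 72 lower, and 76 higher and 55 lower with library size only. The groups' libraries did not overlap in 88 of them, those named included, and in 600 of all tested genes, where chance gives 1.59%. DESeq2 called 217 genes, a model of only both compared groups 45, the model with the marker score 78, and without normal-diet libraries 1 and 5 there were 54. Leaving out normal-diet library 5 gave 63 and leaving out week 3 library 2 gave 61.

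Of the cholesterol list, 18 of 25 members were lower at week 3. Over all members the median was -1.63 (adjusted p = 6.0e-79, or 1.6e-04 with an estimated correlation), and 23 passed adjusted over the list alone. Xenobiotic metabolism had 4 of 26 lower (5 adjusted over the list alone, median -0.18, adjusted p = 1.8e-05, or 0.157 with an estimated correlation), among them Ces2a (-1.08 ± 0.16) and Ugt2b5 (-0.66 ± 0.13). Oxidative stress had 2 of 22 lower (6 adjusted over the list alone, median -0.37, adjusted p = 2.7e-04, or 0.157 with an estimated correlation), the glutathione transferases Gstm3 (-1.71 ± 0.31) and Gstm1 (-1.02 ± 0.22). One-carbon metabolism had 2 of 20 lower (4 adjusted over the list alone, median -0.18, adjusted p = 1.6e-05, or 0.206 with an estimated correlation). In fatty acid synthesis 1 of 19 was lower, Acss2 (-1.77 ± 0.26) (2 adjusted over the list alone, median -0.28, adjusted p = 0.0474, or 0.737 with an estimated correlation). Lipoprotein export had 1 of 18 higher, Abcg8 (1.41 ± 0.25). For the whole list the median was 0.15 (adjusted p = 0.00783, or 0.558 with an estimated correlation), with 4 adjusted over the list alone. In the acute phase list Lcn2, lipocalin 2, was higher (3.41 ± 0.70) and 5 of 24 were so adjusted over the list alone (median 0.26, adjusted p = 0.0352, or 0.737 with an estimated correlation). The fatty acid synthesis call was lost without normal-diet library 3 (camera adjusted p = 0.856), and the acute phase call without week 3 library 1 (0.435), each with the direction turned. The 12 other called lists had 0 of 243 members past the edgeR threshold (82 at an unadjusted p under 0.05, 10 in DESeq2, 0 in voom). They were the 4 marker lists, chemokines (0.29, direction turned with the marker score), injury and YAP targets (0.39), fatty acid oxidation (0.10), secreted proteins (-0.15, 2 lower adjusted over the list alone), periportal zonation (-0.40, 8 lower adjusted over the list alone), the urea list (-0.33, 10), oxidative phosphorylation (-0.21) and ribosomal proteins (-0.24, 11). Cholesterol alone of the 19 lists called, 9 up and 10 down, held with an estimated correlation, and those 12 had adjusted p from 0.0738 to 0.619 with an estimated correlation.

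At week 4 more genes differed than at weeks 1 to 3. Cd36, a fatty acid uptake receptor, was higher (2.03 ± 0.22, from a mean of 12.8 to 52.4 CPM). Apoa4 went from 17.7 ± 12.7 to 152 ± 39.7 CPM (3.10 ± 0.41) and Cfd to 49.3 ± 1.36 CPM (6.02 ± 0.79). Col3a1, a fibrillar collagen gene and a stellate cell marker, was higher (2.45 ± 0.58), with Adam11 (2.35 ± 0.28) and Tmem86a (2.04 ± 0.31). The largest falls were Sqle (-3.72 ± 0.25), Cyp51 (-2.75 ± 0.29) and Fdps (-2.65 ± 0.28) of sterol synthesis, the fatty acid binding protein gene Fabp5 (-3.31 ± 0.41), Cyp3a11 (-2.73 ± 0.45) and Cyp2c40 (-3.33 ± 0.83), whose reads may be shared with other Cyp2c genes. The marker score in these libraries was 4.69 ± 0.522 against 3.20 ± 0.736 on normal diet (log2 CPM, SD, n = 3 and 5).

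There were 983 genes at week 4 (edgeR, Benjamini-Hochberg adjusted p from 5.0e-10 for Sqle to 0.0219 for Cyp2c40 among those named), 644 higher and 339 lower, and 1033 higher and 150 lower with library size only. In 692 of them the libraries of both groups did not overlap, those named included, and in 1608 of all tested genes, where chance gives 3.57%. With the marker score as a term 51 genes were called, and without normal-diet libraries 1 and 5, 198. The count was 155 without week 4 library 1 and 293 without its library 2, 421, 632 and 554 without normal-diet library 1, 2 or 5, 243 with only both compared groups and 335 with the replicate numbers as a block.

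Cholesterol genes were lower in 23 of 25. Adjusted over the list alone, 24 passed, and the median was -1.83 (adjusted p = 4.7e-56, or 0.00165 with an estimated correlation). In the male-biased list, genes with higher liver expression in males, 8 of 20 were lower (14 adjusted over the list alone, median -0.92, adjusted p = 1.7e-10, or 0.190 with an estimated correlation), including Nudt7, a peroxisomal CoA hydrolase (-0.93 ± 0.16), Cyp7b1 (-1.42 ± 0.31) and Cyp4a12a (-1.02 ± 0.23). Complement and coagulation had 8 of 27 lower, such as Hc (-0.69 ± 0.17), C8b (-1.11 ± 0.28) and Masp2 (-0.41 ± 0.11). The list median was -0.36 (adjusted p = 1.1e-08, or 0.190 with an estimated correlation), with 17 adjusted over the list alone. With library size only 2 of the complement genes were lower and the median was -0.20. Bile acid synthesis and transport had 4 of 21 lower (4 adjusted over the list alone), among them the bile salt export pump Abcb11 (-0.75 ± 0.15), with a median of -0.12 that turned positive with library size only (adjusted p = 0.0490, or 0.347 with an estimated correlation). Fatty acid oxidation had 2 of 24 higher, Vnn1 (1.26 ± 0.26) and Acot2 (0.98 ± 0.29). Its median stood at 0.25 (adjusted p = 0.0145, or 0.392 with an estimated correlation), and 2 passed adjusted over the list alone.

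The list of injury and YAP targets had 6 of 16 higher and 1 lower at week 4, with Ly6d (2.19 ± 0.50), Ccn2 (2.39 ± 0.61) and Klf6 (0.99 ± 0.26). As a list it had a median of 0.87 (adjusted p = 9.5e-04, or 0.0952 with an estimated correlation), and 6 and 2 such members adjusted over the list alone. Cytoskeleton genes were higher in 7 of 23 (12 adjusted over the list alone, median 0.41, adjusted p = 1.8e-04, or 0.347 with an estimated correlation), such as Anxa2 (1.56 ± 0.26), S100a6 (2.14 ± 0.49) and Tuba1a (1.41 ± 0.33). Chemokines and NF-kB targets were higher in 5 of 19, such as Ccl2 (2.13 ± 0.58), Cxcl2 (2.14 ± 0.62) and Vcam1 (1.63 ± 0.49). Over all members the median was 0.51 (adjusted p = 2.6e-04, or 0.347 with an estimated correlation), and 6 passed adjusted over the list alone. The endothelial, Kupffer and stellate marker medians of 1.25, 1.26 and 1.84 stood beside these in the same libraries. List directions turned with the marker score as a term for chemokines (camera adjusted p = 0.704), cytoskeleton (0.812), bile acid genes (0.696) and the urea list (0.704). Xenobiotic metabolism had 2 of 26 lower, secreted proteins 2 of 18, periportal zonation 2 of 20, the urea list 1 of 24, one-carbon metabolism 1 of 20 and ribosomal proteins 3 of 27 (adjusted over the list alone 3, 8, 2, 1, 5 and 4). Their medians were -0.19, -0.27, -0.26, -0.20, -0.22 and -0.21, with adjusted p = 0.0134, 0.00188, 0.00178, 0.00532, 0.00300 and 1.9e-04. Each of these calls was lost with an estimated correlation (adjusted p of 0.554 for the urea list and 0.347 for the others). Endoplasmic reticulum stress (-0.33, adjusted p = 0.00804, or 0.554 with an estimated correlation) and oxidative phosphorylation (-0.11, positive with library size only, adjusted p = 0.0282, or 0.595 with an estimated correlation) were called with 0 of 47 members past the edgeR threshold (8 at an unadjusted p under 0.05, 1 in DESeq2, 0 in voom). Of 20 lists called, 8 up and 12 down, cholesterol alone held with an estimated correlation.

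At weeks 5 and 6 the number of genes that differed from normal diet was at its highest, although with the marker score as a term it was at its lowest. Fibrillar collagen and macrophage transcripts were among the largest rises: Col3a1 went from 2.92 ± 0.801 CPM (SD, n = 5) to 52.4 ± 29.1 CPM at week 5 and 38.6 ± 13.1 at week 6 (SD, n = 3 each; log2 fold changes 4.13 ± 0.56 and 3.70 ± 0.56). Lgals3, galectin 3, went from 8.89 ± 6.28 to 79.6 ± 12.8 and 82.7 ± 11.9 CPM, and Clec7a, which encodes a receptor of myeloid cells, was higher too (2.99 ± 0.50 and 3.32 ± 0.51). Cfd (4.22 ± 0.85 and 5.52 ± 0.80), Col1a2 (3.64 ± 0.60 and 3.15 ± 0.60), at week 5 Fabp4 (3.02 ± 0.48) and at week 6 Apoa4 (2.85 ± 0.41) completed the largest rises that the rule names. Sterol genes remained among the largest falls, with Sqle (-4.23 ± 0.26 and -3.83 ± 0.25), Fdps (-3.13 ± 0.29 and -2.77 ± 0.29) and Msmo1 (-2.88 ± 0.32 and -2.95 ± 0.32) at weeks 5 and 6. Others were Cyp51 at week 5 (-2.86 ± 0.29) and Fabp5 at week 6 (-2.71 ± 0.40). Cyp2c40 (-4.37 ± 0.92 and -4.64 ± 0.97) and the major urinary protein gene Mup15 (-3.11 ± 0.75 and -3.02 ± 0.75) were lower too, although reads may be shared among the close paralogs of both families. In these libraries the marker score was 5.71 ± 0.169 and 5.46 ± 0.166 against 3.20 ± 0.736 on normal diet (log2 CPM, SD).

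The counts were 4197 genes at week 5, 2268 higher and 1929 lower, and 3175 at week 6, 1929 higher and 1246 lower (edgeR, Benjamini-Hochberg adjusted p for Sqle 7.4e-11 and 4.6e-10, and for Col3a1 2.4e-05 and 1.1e-04). With library size only they split into 3790 higher and 364 lower at week 5 and 3269 and 229 at week 6. Both groups' libraries did not overlap in 3742 of the week 5 and 2607 of the week 6 genes, those named included, and in 4547 and 3160 of all tested genes, where chance gives 3.57%. At least 2-fold changes were 2002 and 1713. With the marker score as a term 10 genes were called at week 5 and 18 at week 6, against 132, 49, 78 and 51 at weeks 1 to 4. Of the 152 gene results named by rule at week 5 and 148 at week 6, 3 and 7 then stayed past the threshold and 19 and 16 turned direction. A model of week 6 and normal diet alone called 2094.

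**Figure D2:**
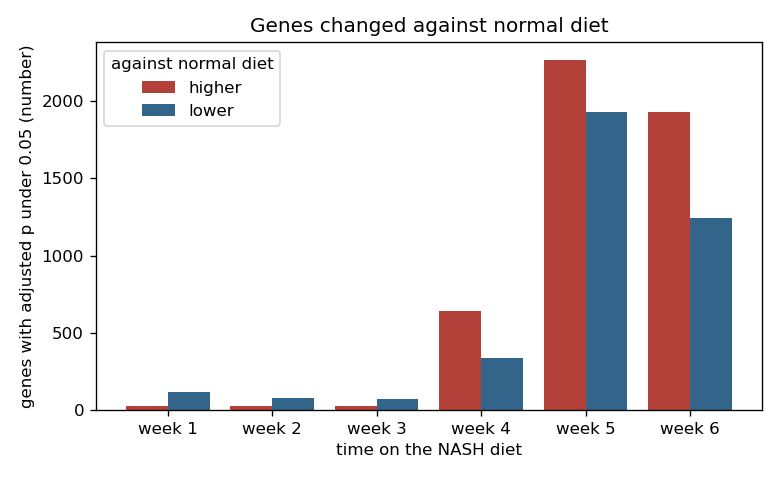
Genes called higher (up) and lower (down) than on normal diet at each week (edgeR, adjusted p under 0.05). The bars go from 26 higher and 116 lower at week 1 to 2268 and 1929 at week 5 and 1929 and 1246 at week 6; with library size only the week 6 split was 3269 and 229.

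The cholesterol list was lower in 25 of 25 members at week 5 and 24 of 25 at week 6 (25 adjusted over the list alone at each). The medians stood at -2.03 and -1.99 (adjusted p = 7.1e-31 and 2.3e-34, or 0.0353 and 0.0235 with an estimated correlation). Lipid droplet and lipid uptake had 6 of 16 higher and 1 lower at week 5 and 5 and 1 at week 6 (7 and 2, then 6 and 1, adjusted over the list alone). The medians were 0.65 and 0.29 (adjusted p = 0.0341 and 0.0445, or 0.235 and 0.240 with an estimated correlation), and Cd36 stood at 70.8 ± 12.7 and 67.7 ± 19.9 CPM and, at week 6, Lpl (1.85 ± 0.30), Fabp4 (2.49 ± 0.48) and Cidec (2.23 ± 0.52). Fatty acid synthesis had 5 and 3 of 19 lower, with Acss2 (-2.30 ± 0.30), Acacb (-1.75 ± 0.36) and Slc25a1 (-0.64 ± 0.19) at week 6. The list medians were -0.60 and -0.61 (adjusted p = 0.0137 and 0.0158, or 0.600 and 0.588 with an estimated correlation), with 4 and 3 adjusted over the list alone. With library size only 3 and 2 of these genes were lower, and the medians were -0.27 and -0.30.

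The list of male-biased genes had 16 of 20 lower at week 5 and 13 of 20 at week 6. Its medians stood at -1.16 and -1.11 (adjusted p = 9.7e-09 and 3.0e-08, or 0.141 and 0.124 with an estimated correlation), and 19 and 16 passed adjusted over the list alone. With library size only 12 and 8 were lower. Nudt7 went from 799 ± 116 to 310.0 ± 26.0 CPM (-1.37 ± 0.16), with Cyp4a12a (-1.25 ± 0.23), Mup11 (-2.57 ± 0.48) and Mup7 (-1.97 ± 0.41) at week 6. At week 5 members lower included Selenbp2 (-2.42 ± 0.43) and Cyp7b1 (-1.74 ± 0.32). The female-biased list was not called, and at week 6 2 of 7 were higher, Ntrk2 (3.18 ± 0.61) and Cux2 (2.54 ± 0.70). Lower were 2, Cyp2c40 (-4.64 ± 0.97) and Cyp2c69 (-5.13 ± 1.19), with a median of 0.08, a mean of -0.57 and camera adjusted p = 0.999. The male-biased list averaged 8.32 ± 0.32 log2 CPM on normal diet (SD, n = 5), 8.55 ± 0.13 at week 1 and 7.26 ± 0.22 at week 6.

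Several secretory and metabolic lists were lower at weeks 5 and 6, and each call in this paragraph was lost with an estimated correlation. Complement and coagulation had 26 of 27 lower at week 5 and 19 at week 6, with Serpinc1 (-0.61 ± 0.10), Plg (-0.59 ± 0.11) and F10 (-0.59 ± 0.13) at week 6. As a list it had medians of -0.69 and -0.46 (adjusted p = 3.7e-11 and 3.4e-08, or 0.0860 and 0.124 with an estimated correlation), and 26 and 23 such members adjusted over the list alone. Secreted proteins had 13 and 12 of 18 lower, such as Fetub (-0.70 ± 0.14) and Itih1 (-0.43 ± 0.10). Over all members the medians were -0.56 and -0.43 (adjusted p = 6.1e-07 and 2.9e-06, or 0.126 and 0.124 with an estimated correlation), and 15 and 16 passed adjusted over the list alone. In the urea list 20 and 17 of 24 were lower, with Cps1 from 1275 ± 212 to 626 ± 176 CPM. Adjusted over the list alone, 22 and 19 passed, and the medians were -0.64 and -0.60 (adjusted p = 5.6e-08 and 3.7e-08, or 0.175 and 0.149 with an estimated correlation). Periportal zonation had 12 lower and 1 higher of 20 at week 5 and 11 lower at week 6 (12 and 1, then 14, adjusted over the list alone). The medians were -0.66 and -0.60 (adjusted p = 2.1e-05 and 1.4e-05, or 0.141 and 0.124 with an estimated correlation), and Cdh1, the gene of E-cadherin, stood at 201 ± 16.8 CPM on normal diet and 113 ± 29.1 at week 6. One-carbon metabolism had 14 and 9 of 20 lower. The list medians were -0.54 and -0.41 (adjusted p = 1.6e-05 and 2.5e-05, or 0.141 and 0.124 with an estimated correlation), with 15 and 15 adjusted over the list alone. With library size only fewer members were lower at weeks 5 and 6: 14 and 2 of complement, 4 and 1 of the secreted proteins, 8 and 5 of the urea list, 7 and 2 of the periportal and 5 and 3 of the one-carbon genes. The week 6 medians were then -0.15, -0.13, -0.29, -0.29 and -0.10.

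Xenobiotic metabolism had 13 and 14 of 26 lower at weeks 5 and 6, with Ces2a from 280.1 ± 55.9 to 91.6 ± 32.5 CPM. Its medians stood at -0.50 and -0.70 (adjusted p = 2.1e-05 and 2.6e-07, or 0.141 and 0.112 with an estimated correlation), and 13 and 15 passed adjusted over the list alone. Bile acid genes were lower in 10 and 9 of 21, such as Cyp27a1 (-1.17 ± 0.19), Abcb11 (-0.77 ± 0.15) and Slc10a1 (-0.71 ± 0.16), and higher in 1. As a list it had medians of -0.51 and -0.55 (adjusted p = 1.8e-04 and 8.7e-05, or 0.126 and 0.124 with an estimated correlation), and 10 and 12 lower members adjusted over the list alone. Oxidative phosphorylation had 19 and 18 of 27 lower, such as Atp5b (-0.48 ± 0.10) and Cox5b (-0.48 ± 0.11), and 0 of 27 at week 6 with library size only. Over all members the medians were -0.41 and -0.40 (adjusted p = 3.1e-06 and 1.2e-07, or 0.176 and 0.124 with an estimated correlation), and 21 and 21 passed adjusted over the list alone. Endoplasmic reticulum stress had 11 and 7 of 20 lower (14 and 14 adjusted over the list alone, medians -0.62 and -0.60, adjusted p = 6.8e-04 and 4.9e-05, or 0.380 and 0.265 with an estimated correlation), with the chaperone gene Hspa5 (-0.81 ± 0.24). With library size only 4 of the xenobiotic, 5 of the bile acid and 0 of the endoplasmic reticulum genes were lower at week 5. It was 6, 3 and 1 of them at week 6, and 0 of the oxidative phosphorylation genes at week 5. Ribosomal proteins had 9 and 5 of 27 lower, and their medians of -0.21 and -0.23 turned positive with library size only (10 and 5 adjusted over the list alone, adjusted p = 0.01 and 0.00250, or 0.381 and 0.287 with an estimated correlation). Pericentral zonation was called down at week 6, with 4 of 19 lower and 1 higher, the same counts adjusted over the list alone (median -0.66, adjusted p = 0.0407, or 0.656 with an estimated correlation). Its direction turned with the marker score as a term (median 0.09, camera adjusted p = 0.302). At week 5 hepatocyte transcription factors had 7 of 22 lower and 1 higher, also over the list alone, with a median of -0.32 that turned positive with library size only (adjusted p = 0.0291, or 0.302 with an estimated correlation), including Thrb (-0.73 ± 0.14) and Cebpa (-0.54 ± 0.12).

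Inflammatory, injury, cytoskeletal and cell cycle lists were higher at weeks 5 and 6. Most started from low levels: on normal diet 3 of 19 chemokine, 4 of 16 injury and 1 of 23 cell cycle members reached at least 10 CPM. Of the cytoskeleton members 16 of 23 did. Chemokines and NF-kB targets had 15 and 12 of 19 higher, such as Ccl2 (3.15 ± 0.56), Cxcl16 (2.12 ± 0.34) and Vcam1 (2.72 ± 0.48). Adjusted over the list alone, 16 and 14 passed, and the medians were 1.45 and 1.25 (adjusted p = 1.1e-06 and 1.4e-06, or 0.148 and 0.131 with an estimated correlation). Injury and YAP targets, of which 5 of 16 are in other lists, had 9 and 9 higher, such as Ly6d (3.34 ± 0.48), Myof (2.52 ± 0.39) and Axl (2.54 ± 0.43). The list medians were 1.15 and 1.21 (adjusted p = 1.3e-04 and 3.5e-05, or 0.0579 and 0.0339 with an estimated correlation), with 9 and 10 adjusted over the list alone. Cytoskeleton had 14 higher and 1 lower of 23 at week 5 and 12 higher at week 6 (14 and 1, then 13 and 1, adjusted over the list alone). The medians were 0.98 and 0.76 (adjusted p = 1.3e-05 and 1.2e-06, or 0.235 and 0.174 with an estimated correlation), such as Anxa2 (2.40 ± 0.25) and S100a11 (2.27 ± 0.30). Cell cycle had 15 and 9 of 23 higher (16 and 12 adjusted over the list alone, medians 1.36 and 1.21, adjusted p = 7.3e-05 and 2.2e-04, or 0.235 and 0.265 with an estimated correlation), including Mcm3, a replication helicase subunit (1.31 ± 0.27), and Ccnd1, cyclin D1 (1.20 ± 0.29). Immediate early and heat shock genes were called at week 5 with 10 of 22 higher (10 adjusted over the list alone, median 0.79, adjusted p = 0.00139, or 0.381 with an estimated correlation), and at week 6 had 4 higher (adjusted p = 0.230, or 0.778 with an estimated correlation). These lists moved beside the marker lists: with the marker score as a term, the week 6 medians of the chemokine, injury, cytoskeleton, cell cycle and lipid droplet lists were -0.03, 0.51, -0.10, -0.28 and -0.05, and at week 5 the cytoskeleton and cell cycle directions turned (camera adjusted p = 0.963 and 0.757). In the same model the week 6 medians of the lower lists were -1.54 (cholesterol), -0.83 (fatty acid synthesis), -0.93 (male-biased), -0.79 (endoplasmic reticulum stress), -0.47 (periportal), -0.38 (xenobiotic), -0.34 (oxidative phosphorylation), -0.34 (ribosomal), -0.26 (bile acid), -0.24 (complement), -0.19 (urea), -0.15 (secreted protein) and -0.05 (one-carbon).

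Of 43 lists, 24 were called at week 5, 10 up and 14 down, and 23 at week 6, 9 up and 14 down. With an estimated correlation the calls that held were cholesterol at week 5 and cholesterol and injury and YAP targets at week 6. Lists not called at any week against normal diet, with their week 6 values, were the integrated stress response (2 higher and 2 lower of 16, median -0.04, camera adjusted p = 0.999), glucose metabolism (5 and 4 of 24, -0.07, 0.961), p53 targets (3 higher of 18, 0.31, 0.280), oncofetal genes (1 and 1 of 6, 0.04, 0.995) and the circadian clock (1 lower of 17, -0.04, 0.737). Named members among them were Sesn2 (1.20 ± 0.30), Pkm (2.25 ± 0.38) and Hk3 (2.53 ± 0.49). Called at an earlier week but not at week 6 were fatty acid oxidation (2 higher and 1 lower of 24, median -0.08, adjusted p = 0.807), lipoprotein export (4 and 3 of 18, -0.18, 0.951), oxidative stress (4 and 3 of 22, -0.07, 0.802) and acute phase proteins (1 and 5 of 24, -0.30, 0.387). So were the interferon response (6 and 1 of 24, 0.02, 0.149), hepatocyte transcription factors (1 and 4 of 22, -0.29, 0.0709) and mitochondrially encoded transcripts (1 lower of 10, -0.21, 0.0735). The lysosome list, called in no week against normal diet, had 7 higher and 1 lower of 21 (0.16, 0.144). For the integrated stress, glucose, circadian, fatty acid oxidation, lipoprotein, oxidative stress and acute phase lists the median was negative and the mean positive at week 6. These medians, and those of the transcription factor and mitochondrial lists, turned with library size only.

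**Figure D3:**
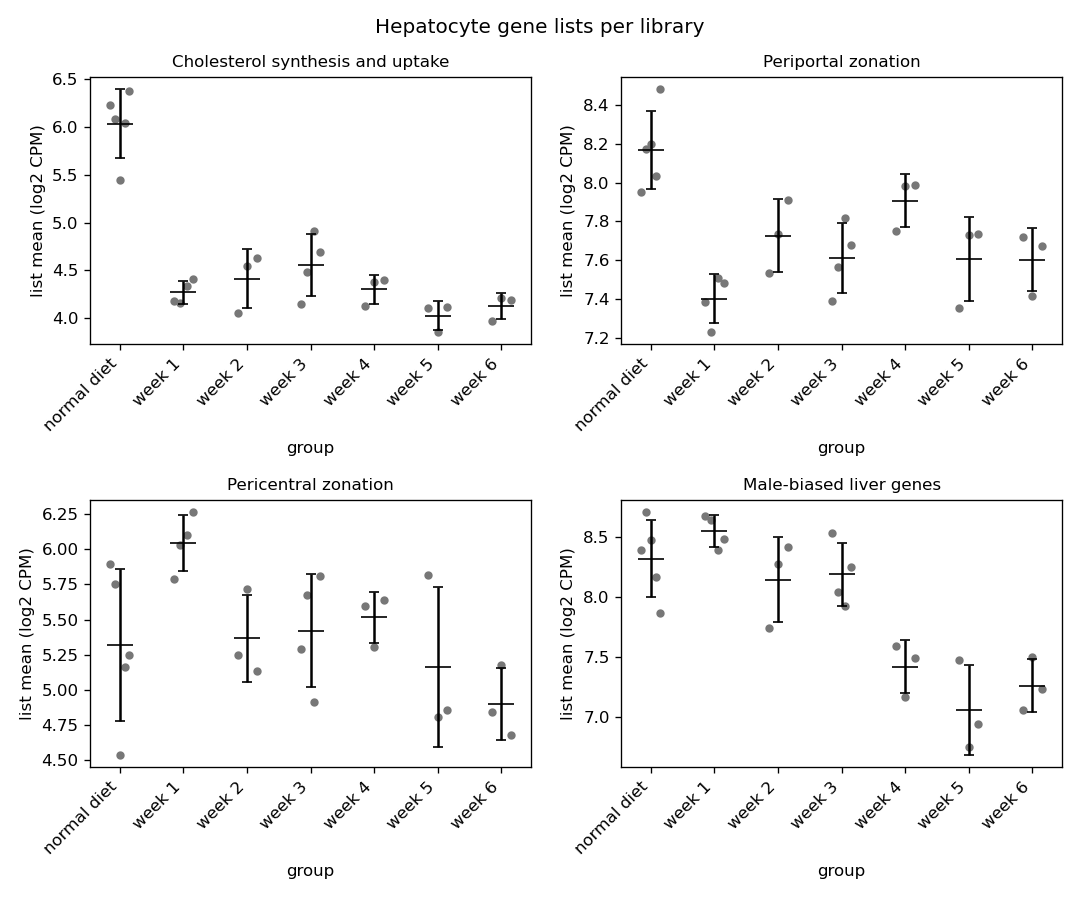
Mean log2 CPM of 4 gene lists (cholesterol synthesis and uptake, periportal zonation, pericentral zonation and male-biased liver genes) in each library, by weeks on the NASH diet, with normal diet at 0. Points are libraries and bars the group mean ± SD; the cholesterol mean was 6.04 ± 0.36 on normal diet and 4.27 ± 0.12 at week 1, and the male-biased mean 8.55 ± 0.13 at week 1 and 7.26 ± 0.22 at week 6.

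Within the NASH-diet mice, the later weeks were set against the earlier ones. Cd36 had the smallest p-value of a difference between the 6 weeks. It went from 15.4 ± 2.68 CPM at week 1 (SD, n = 4) to 70.8 ± 12.7 at week 5 (SD, n = 3). Meis2, a homeobox transcription factor gene, went from 7.42 ± 1.91 to 34.5 ± 4.29 CPM, and Rspo3, a Wnt signal enhancer, from 5.83 ± 1.29 to 23.0 ± 4.54. Anxa2 went from 7.97 ± 2.69 to 24.2 ± 7.77 CPM, while Serpina1e, an alpha-1-antitrypsin gene with close paralogs, went from 14194 ± 658 to 3399 ± 545 CPM. Against week 1, week 6 was highest for Cfd (3.27 ± 0.69), the retinoic acid hydroxylase gene Cyp26b1 (2.49 ± 0.69), the stellate cell globin Cygb (2.42 ± 0.43), Fabp4 (2.34 ± 0.51), Lgals3 (2.34 ± 0.54) and Col3a1 (2.32 ± 0.54). It was lowest for Cyp2c40 (-5.22 ± 0.99) and 5 Mup genes, from Mup15 (-4.04 ± 0.80) to Mup9 (-3.02 ± 0.86), whose reads may be shared.

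The weeks differed in 2749 genes (edgeR, Benjamini-Hochberg adjusted p = 1.5e-06 for Cd36 and Meis2, 3.1e-05 for Slc9a3r2 and 4.4e-05 for Serpina1e, Anxa2 and Rspo3). A linear trend over weeks was called in 4020, 2246 up and 1774 down (3114 and 430 with library size only), of which 17 changed at least 2-fold per week, 3 upward and 14 downward. Among genes with a mean of at least 10 CPM, a floor that most of these 17 lie under, the steepest were Fabp4 (0.63 ± 0.09), Col3a1 (0.56 ± 0.09), Lgals3 (0.54 ± 0.09), Fcgr2b (0.54 ± 0.07), Clec14a (0.54 ± 0.06) and Arrb1 (0.52 ± 0.07) upward, in log2 per week. Downward they were Cyp2c40 (-1.06 ± 0.17), Mup15 (-0.85 ± 0.14), Mup17 (-0.72 ± 0.12), Mup16 (-0.65 ± 0.10), Mup11 (-0.65 ± 0.09) and Mup9 (-0.63 ± 0.15). Week 6 differed from week 1 in 1956 genes, 1363 higher and 593 lower (1791 and 184 with library size only). In 1798 of them the libraries did not overlap, those named above included, and in 2924 of all tested genes, where chance gives 5.71%. With the marker score as a term edgeR called 0 genes among weeks (759 at an unadjusted p under 0.05, 0 in voom) and 1 with a trend, Cd36. At week 6 against week 1 it called 0 (1005 at an unadjusted p under 0.05, 0 in voom). The week 6 against week 1 count was 1279 and 1232 without week 1 library 2 or 4 and 1227 without week 6 library 1.

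Of the lists, 19 were called at week 6 against week 1, 10 up and 9 down, and 0 held with an estimated correlation. Pericentral zonation had 12 of 19 lower (14 adjusted over the list alone, median -1.19, adjusted p = 3.6e-08, or 0.224 with an estimated correlation), with Cyp1a2 (-2.25 ± 0.48) and Gulo (-1.67 ± 0.40). Male-biased genes were lower in 16 of 20, with Nudt7 (-1.12 ± 0.17), Hsd3b5 (-1.91 ± 0.35) and Slco1a1 (-0.94 ± 0.17). For the whole list the median was -1.10 (adjusted p = 1.6e-14, or 0.105 with an estimated correlation), with 17 adjusted over the list alone. Complement and coagulation had 14 of 27 lower (18 adjusted over the list alone, median -0.42, adjusted p = 2.1e-09, or 0.126 with an estimated correlation). With library size only 8 of them were lower, with a median of -0.24. Cytoskeleton had 13 of 23 higher. Adjusted over the list alone, 15 passed, and the median was 0.90 (adjusted p = 1.5e-09, or 0.190 with an estimated correlation). The endothelial markers were higher in 16 of 18. The list median was 1.60 (adjusted p = 1.1e-13, or 0.206 with an estimated correlation), with 18 adjusted over the list alone. The cholesterol list, by contrast, did not pass (0 of 25 in edgeR, DESeq2 and voom, 2 at an unadjusted p under 0.05, median -0.11, positive with library size only, camera adjusted p = 0.262). Nor did the female-biased list (4 higher and 2 lower of 7, median 1.85, mean -0.32, 0.665), whose lower members were Cyp2c genes. Neither did periportal zonation (4 higher and 2 lower of 20, median 0.08, 0.742). For the trend 22 lists were called, 11 up and 11 down, 0 of which held with an estimated correlation. The male-biased list had 16 of 20 lower (20 adjusted over the list alone) and a median of -0.25 per week (adjusted p = 6.3e-15, or 0.0737 with an estimated correlation).

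Across all 6 weeks, 49 genes were called in one direction at each week against normal diet, 43 lower and 6 higher. Of the 43, 18 belong to the cholesterol list, such as Sqle, Fdps and Lss. The 6 higher were Abcg8, Adam11, Fabp2, Plagl1, Slc17a8 and Tmem86a, of which Plagl1 is named after its values were seen. The overlap was 28 genes without normal-diet libraries 1 and 5, and 6 with the marker score as a term.

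Weeks 5 and 6 shared 2824 called genes in the same direction, 1812 higher and 1012 lower, where 369 and 203 would be shared by chance. Since every week is set against the same 5 normal-diet libraries, their fold changes correlate in part for that reason: r across genes was 0.945, against 0.411 in the simulations, and genes are not independent replicates. With weeks 5 and 6 set against separate normal-diet libraries (2 and 3), 1813 genes were shared and r was 0.834. Weeks 1 and 2 shared 68 genes, 8 higher and 60 lower (r = 0.740, and 0.425 in the simulations), and 32 with separate normal-diet libraries (r = 0.507). Weeks 1 and 6 shared 111 genes, 18 higher and 93 lower, where chance gives 4.23 and 12.2 (r = 0.469, 0.420 in the simulations). With separate normal-diet libraries it was 46 (r = 0.470).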

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

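Tests chosen only after the result was seen were those of RNA from other cells as a part of the cause, of a fixed proportion of other cells, of dilution for the male-biased list and of reads shared among Mup genes, together with the models holding the marker score.

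Single libraries lay apart from their group in 6 of 141 measures tested in groups of 4 or 5 libraries (by Dixon's gap test on list means, total counts, genes detected, mitochondrial share and composition factor), where chance gives about 1 in 20. The 6 were list means, in log2 CPM. Normal-diet library 3 had a fatty acid synthesis mean of 7.68 (the nearest library 6.54) and normal-diet library 4 a bile acid mean of 6.96 (nearest 7.13). Week 1 library 1 stood at 7.07 for endoplasmic reticulum stress (nearest 6.80). Week 3 library 2 stood apart in 3 lists: interferon response 5.11 (nearest 4.64), glucose metabolism 5.47 (nearest 5.32) and Kupffer cell markers 5.54 (nearest 5.00).

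Weeks 6 and 1 on the diet differed in a direct test, with 1956 genes (edgeR) and 19 lists (camera). The normal-diet libraries form 1 group without a match for each week. Time on the diet therefore cannot be told apart from other differences between these groups, such as age. The list medians of week 6 less week 1 were, for markers, 1.26 (Kupffer cells), 1.82 (monocytes, macrophages and dendritic cells), 1.60 (sinusoidal endothelial cells) and 1.63 (stellate cells). Other lists higher at week 6 were chemokines and NF-kB targets (0.94), cytoskeleton (0.90), cell cycle (0.81), injury and YAP targets (0.46), oxidative stress (0.32) and lysosome and autophagy (0.23). Lower ones were pericentral zonation (-1.19), male-biased genes (-1.10), xenobiotic metabolism (-0.60), endoplasmic reticulum stress (-0.53), complement and coagulation (-0.42), bile acid synthesis and transport (-0.38), hepatocyte transcription factors (-0.30), secreted proteins (-0.27) and oxidative phosphorylation (-0.22). With an estimated correlation 0 of these 19 calls held (the smallest adjusted p = 0.105).

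The genes higher at week 6 came with markers of endothelial, Kupffer and stellate cells, although the cells had been sorted as hepatocytes. Within groups, the 1859 higher genes outside the marker lists followed the marker score (median correlation 0.572, against -0.00606 in matched genes not called), so RNA from other cells is likely a part of the cause. Whether the other cells kept a fixed proportion stays open. Endothelial markers rose by 1.14 log2 more than cholangiocyte markers (list means 1.39, SE 0.489). The cholangiocyte list cannot decide this: 1 of its 7 tested members reached 10 CPM on normal diet, and 4 are also in the injury list. The Kupffer, endothelial and stellate medians were 2.04, 1.94 and 2.38. Whether such RNA is the whole cause cannot be told apart from a change in hepatocytes: with the score in the model the median log2 fold change went from 1.86 to 0.279 and its median SE from 0.396 to 0.559, 3 genes stayed called, and 78.7% of the variance of the score lies between the groups. A response of hepatocytes to weeks of diet, or of the other cells in these mice, also stays open and untested.

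The cholesterol genes were lower from week 1 on. Dilution by RNA from other cells is argued against, since with the marker score in the model the week 6 median was -1.54 (-1.99 without it; list mean -1.43, SE 0.302) and from -1.84 to -1.34 with each library left out in turn. Of 25 members 5 were called lower then (2 to 10 over the libraries left out) and 24 without the score, as standard errors grew. Nor was it a property of a few normal-diet libraries, as the week 1 median was -1.92 against 2 of them and -1.78 against the other 3. A response to the diet, through the feedback by which sterol supply lowers the synthesis genes, may explain it as a hypothesis. The composition of the diet is not given in the sources used here, and sterol levels were not measured.

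The male-biased genes were lower at week 6. Reads shared among Mup genes are argued against as the cause, since the median of the 14 members outside that family was -1.20, with 10 of them called lower. Dilution by RNA from other cells is argued against as the whole cause, since with the marker score in the model the list mean was -0.91 (SE 0.360; -1.06, SE 0.204, without it). With each library left out in turn it ran from -1.06 to -0.66, at least 2.08 standard errors below 0. With each library kept the median was -0.93 (-1.11 without the score), although 1 of 20 members was called lower (at most 2 over the libraries left out) and 13 without the score, as the median SE grew from 0.331 to 0.537. The list median also lay -0.68 log2 from that of the secreted hepatocyte proteins (list means -0.63, SE 0.220). Dilution as a part of the fall stays open, since the score differs between the groups. A change in the hormonal control of these genes on the diet might contribute and was not tested.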

How the results depend on the processing

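Tests chosen only after the data were seen were those with the marker score as a term, without normal-diet libraries 1 and 5, without mitochondrially encoded genes and with libraries thinned to the smallest total. Where no reason is given the cause was not tested.

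Of 612 named gene results, 365 kept their direction and stayed past the threshold under each alternative but the 4 just named, and 61 with these counted too. Of 20140 comparisons without these 4, 18907 did, 1231 fell short of the threshold and 2 turned. Both that turned were at week 6 with library size only, Rpl32 (log2 fold change 0.0151) and Rpl7 (0.0319), which the shift of all genes under that scaling accounts for by construction. Lists were run with library size only, the block, each library left out, an estimated correlation, fry and the 4 added alternatives. Of 121 list calls, 10 kept through each of these, and of 3992 comparisons 3657 kept direction and threshold, 308 fell short and 27 turned. Leaving out mitochondrial genes kept each of the 120 lists then tested, and thinning 118 of 121. Of the named gene results they kept 605 of 609 and 589 of 610, and leaving out normal-diet libraries 1 and 5 kept 494 of 612.

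The marker score as a term left 87 of the 612 past the threshold, while 475 fell short and 50 turned, each of the 50 short of the threshold. At week 4 the log2 fold changes that turned were those of Cxcl2 (-0.00726), Vcam1 (-0.0341), Clec4f (-0.0849), Lyz2 (-0.190) and 2 more (-0.222, -0.106). At week 5 they were Lgals3 (-0.226), Cxcl16 (-0.0592), Vcam1 (-0.104), mt-Rnr1 (0.0758), mt-Rnr2 (0.105), Ccnd1 (-0.0265), Axl (-0.232), Cux2 (-0.600), Clec4f (-0.245), Ptprc (-0.530) and 9 more (-0.0855, -0.648, -0.0946, -0.749, -0.805, 0.0733, -0.344, -0.301, -1.004). At week 6 they were Ccnd1 (-0.0706), Axl (-0.0160), Cux2 (-0.312), Clec4f (-0.233), Ptprc (-0.311) and 11 more (-0.191, -0.390, -0.00264, -0.0674, -1.19, -0.371, -0.00265, -0.0843, -0.311, -0.277, -0.0566). For week 6 against week 1 they were Cxcl2 (-0.00993), Ccl2 (-0.345) and 7 more (-0.0925, -0.301, -0.00772, -0.185, -0.232, -0.379, -0.0622).

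DESeq2 called 267, 198 and 217 genes at weeks 1, 2 and 3 against 142, 105 and 101. With only both compared groups in the model, which leaves fewer libraries to estimate the spread, the counts were 58 at week 2, 45 at week 3, 243 at week 4 and 2094 at week 6. With the replicate numbers as a block they were 59 at week 2 and 335 at week 4. Libraries of the same number did not resemble each other (median correlation of deviations -0.0050 over 66 pairs, and -0.0026 over 200 pairs of other numbers).

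A threshold of 0.01 gave 81, 44, 53, 174, 2756 and 1994 genes at weeks 1 to 6, 1473 among weeks, 2589 for the trend and 838 for week 6 against week 1. At least 2-fold changes numbered 85, 63 and 61 at weeks 1 to 3, 2002 and 1713 at weeks 5 and 6, 17 for the trend (per week) and 1233 for week 6 against week 1. Both follow from the stricter rule.

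With the marker score as a term the counts were 132, 49, 78, 51, 10 and 18 at weeks 1 to 6, 0 among weeks in edgeR (759 at an unadjusted p under 0.05, 0 in voom), 1 for the trend, 0 for week 6 against week 1 (1005 unadjusted, 0 in voom), 6 for the overlap of all weeks and 13 lists at week 6. The score differs between the groups, so it takes up their difference in part. Without normal-diet libraries 1 and 5, and so with fewer libraries, the counts were 84, 51, 54 and 198 at weeks 1 to 4 and 28 for the overlap.

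Lists called with an estimated correlation numbered 4, 1, 1, 1, 1 and 2 at weeks 1 to 6, and with fry 7, 8, 10, 19, 27 and 27 (camera 20, 15, 19, 20, 24 and 23). List directions turned with the marker score, with adjusted p at week 1 for monocyte (0.255) and endothelial markers (0.0526), at week 2 for chemokines (0.670), Kupffer (0.322), monocyte (0.00744) and endothelial markers (0.00790), and at week 3 for chemokines (0.759), endothelial (0.595) and stellate markers (0.946). At week 4 they turned for bile acid genes (0.696), chemokines (0.704), the urea list (0.704), cytoskeleton (0.812), Kupffer (0.00351) and monocyte markers (0.00351). At week 5 it was cell cycle (0.757), cytoskeleton (0.963), Kupffer (1.5e-05) and monocyte markers (0.0211), and at week 6 pericentral zonation (0.302), cell cycle (0.580), Kupffer (9.9e-04) and monocyte markers (0.565). The Kupffer, endothelial and stellate lists make up the score itself. Without normal-diet libraries 1 and 5, monocyte (0.925) and endothelial markers (0.263) turned at week 1. Without normal-diet library 3 fatty acid synthesis turned at week 3 (0.856; from 4.0e-04 over the libraries left out in turn), and without week 3 library 1 so did acute phase proteins (0.435, lowest 1.8e-05).

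Leaving out each library in turn gave 93 to 162 genes at week 1, 44 to 123 at week 2, 61 to 132 at week 3, 155 to 1360 at week 4, 3139 to 4399 at week 5 and 2439 to 3300 at week 6, with 1876 to 2916 among weeks, 3141 to 4207 for the trend and 1227 to 2049 for week 6 against week 1. The libraries that moved a count by over 1.5 times were normal-diet library 5 (94) and week 1 library 2 (93) at week 1, week 2 libraries 1 (44) and 2 (53) at week 2, normal-diet library 5 (63) and week 3 library 2 (61) at week 3, week 4 libraries 1 (155) and 2 (293) and normal-diet libraries 1 (421), 2 (632) and 5 (554) at week 4, and week 1 libraries 2 (1279) and 4 (1232) and week 6 library 1 (1227) for week 6 against week 1. List counts ran from 14 to 21, 12 to 19, 15 to 22, 19 to 24, 23 to 25 and 21 to 25 at weeks 1 to 6, and the overlap from 34 to 64.

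With libraries thinned to the smallest total the counts at weeks 1 to 6 were 147, 100, 108, 898, 3890 and 2930 genes. Simulated 1.5-fold changes were recovered in 23.9% of genes at the week 1 group sizes and 20.9% at those of week 6, at these totals and this spread between libraries, whose parts in that limit were not separated.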

Other observations

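Of the tests in this part, the models with the marker score were chosen only after the data were seen.

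The real grouping was set against other splits of the same libraries. At week 1 it gave 142 genes and the highest other of 100 splits 52, at week 3 101 and 17 (1 of 100 splits as large, the real one, in both), so chance is unlikely. At weeks 4, 5 and 6 it gave 983, 4197 and 3175, and the highest others of 56 splits 535, 1788 and 1329, so chance is unlikely. At week 2, 2 of 56 splits were as large, the real one (105) and another (110). That other split had normal-diet libraries 1, 2 and 5 (marker scores 2.26 to 3.48) as its week 2 arm. Its normal-diet arm held all others (3.52 to 4.77). It is largely the real contrast with its sign turned, but also sorts the libraries by marker score. By the share, chance is unlikely at week 2. At weeks 4 and 6 the highest other split put the same 3 normal-diet libraries in the diet arm, and at week 5 libraries 1, 3 and 5. In each, all libraries of that week were in the normal-diet arm, and fewer genes were called than with the real grouping. Among weeks the real value was 2749 and the highest other of 100 splits 2447, and for the trend 4020 and 1709. For week 6 against week 1 it was 1956 and 1125 of 35 splits. Chance is unlikely in each (1 split as large, the real one), but so few splits cannot exclude it.

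Transcripts of the sex chromosomes were read in each library: Xist, which is expressed from the inactive X chromosome of females, had between 0 and 6 counts, and Ddx3y, a gene of the Y chromosome, between 412 and 845. The labels give no sex.

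With the marker score as a term, Cd36 was the 1 gene with a called trend over weeks (0.37 log2 per week, edgeR adjusted p = 0.020), and Sqle stayed called at week 6 (-3.89, adjusted p = 1.2e-06). Of the 18 genes then called at week 6, 3 were higher and 15 lower.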
